A study of Homo sapiens with 8 samples.

How the data were processed

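RNA from human embryonic stem cells was sequenced in 8 libraries, from polyadenylated RNA per the labels' protocols; the values themselves do not establish this for the H1 libraries. Of these, 6 came from H9 cells and 2 from H1 cells, both established human embryonic stem cell lines. The cells carried no transgene (wild type, WT), a doxycycline-inducible Cas9 (iCas9) or a doxycycline-inducible catalytically dead Cas9 (idCas9), brought in with a piggyBac transposon that also carried the rtTA activator, per the labels' protocols. H9 WT, iCas9 and idCas9 cells were each sampled with and without doxycycline. H1 WT and iCas9 cells were sampled with doxycycline. The dose and duration of doxycycline were not given in the sources used here. The labels name no separate clones or repeat cultures, so the replicates may be technical and p-values measure only the spread between these libraries.

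The authors deposited 1 table of RPKM (reads per kilobase of exon, scaled to the reads assigned to genes in each library) for 60617 genes, with no further scaling visible. Per the submitters' processing notes, hg38, FastQC, MultiQC, Trim Galore, STAR and featureCounts were used, with no versions or settings given. Strand setting, duplicate handling and annotation release were not given in the sources used here. Without a stated strand setting, reads of overlapping genes, such as MT-ATP8 and MT-ATP6 or a small RNA inside its host gene, cannot be told apart. Near-identical copies such as CSAG1 and CSAG3 or LEFTY1 and LEFTY2 may likewise share reads. RNAs under 200 nt are a further limit, since their RPKM rests on few reads.

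Gene identifiers were joined to GENCODE release 29 (GRCh38, the build named hg38), which gave symbol, type, coordinates and union exon length for 58542 of them. The other 2075 kept their identifier or took a name from a table of gene names. The value of 1 read was recovered from genes with low RPKM: RPKM times exon length fell within 0.01 of a whole number of reads for 73.9% to 75.0% of the checked genes in the H9 libraries and for 82.9% and 83.7% in the H1 libraries. This gave 23.9 M to 27.6 M assigned reads per H9 library (M for mega), and 25.1 M and 22.1 M in H1 iCas9 and H1 WT. The recovered reads served to state the depth of libraries and of genes with few reads, and entered no test, since too few values came out whole for a count test. The Cas9 and rtTA transgenes were not analysed here, so no transgene level checked the labels.

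Tests used log2(RPKM + 1), so fold changes of genes with low values are understated. limma 3.58.1 in R 4.3.3, with a mean-variance trend, was run on genes with a mean of at least 1 RPKM over the libraries compared, with Benjamini-Hochberg adjustment and significance at an adjusted p under 0.05. The 3 fits fixed before the data were examined were iCas9 against WT with doxycycline over H9 and H1 (4 libraries, parent line as a block), doxycycline over the 3 H9 lines (6 libraries, line as a block), and induction of Cas9 or dCas9 (8 libraries; terms for parent line, both constructs and doxycycline). Another 3 fits were added after seeing the data: iCas9 against WT, idCas9 against WT and iCas9 against idCas9 in H9, over the 6 H9 libraries with doxycycline as a term. In these the replicates of a line are its libraries with and without doxycycline. The remaining 9 comparisons have 1 library per arm and no p-value. They are described by the number of genes differing at least 2-fold.

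The blocks were checked by correlating deviations from the group means across genes between libraries of the same cell line. The correlation was 0.717 for the iCas9 pair, 0.582 for the idCas9 pair and 0.608 for the WT pair in H9, and 0.922 for H9 iCas9 and WT set against H1. The last value holds the gap in the shape of values between the H9 and H1 libraries. It was therefore bound to be high and is no separate check of the pairing. Pairing comes from the labels, which name the cell line of each library. With no replicate block, limma called 0 genes for iCas9 against WT and 0 for doxycycline, as it did with the block; the unadjusted counts fell to 2 higher and 0 lower, and to 113 higher and 67 lower.

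Before the data were examined, 42 gene lists were fixed, with 1078 entries of which 1048 matched the table. Lists with at least 5 expressed members (38 to 40 per fit) were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. The second form takes its degrees of freedom from the residuals of the fit, which were 1 or 2. It could therefore hardly call any list. A lack of calls there does not decide whether a list shifted, and leaves the calls at the preset correlation unchecked. For comparisons of 1 library with 1 library, a list's median was ranked among 10000 random lists of equal size matched on expression in 10 bins. Such percentiles describe the libraries and are not tests.

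Named genes followed a rule fixed beforehand. For each limma fit it took the 10 largest changes in each direction among genes past the threshold that moved the same way in every pair; where fewer than 5 passed, the 5 with the smallest p were named and are said not to pass. For doxycycline in each H9 line and for iCas9 against WT in H9 and H1, it took the 8 largest differences in each direction, and for the other pairs of libraries the 5 largest. It added the 2 to 4 members of each described list with the largest change. Genes without a symbol, pseudogenes and sex-linked marker genes of the kind used for sample identity were left out. The rule picked mostly RNAs under 200 nt in the 1 against 1 comparisons, so protein-coding genes are also given there; these were chosen after their values were seen.

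Alternatives were a pseudocount of 0.1, no filter, a filter at 5 RPKM, median-of-ratios scaling, limma without the trend, each library left out in turn, and a 1.5-fold limit. Restriction to protein-coding genes, restriction to genes with at least 200 nt of exons, and list tests of induction without the H1 libraries were added after seeing the data. A scan for chromosome segments was also added then: for each chromosome the breakpoint that best separated the protein-coding log2 differences was found, and gene order was permuted 1000 times. Each limma fit was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 1% and 66% of them for iCas9 against WT over H9 and H1, 6% and 74% for induction, 99% and 100% for doxycycline, 91% and 99% for the iCas9 line, 85% and 99% for the idCas9 line, and 93% and 100% for iCas9 against idCas9. Joins, correlations and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.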

Results

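Transcript levels were measured in 8 libraries of human embryonic stem cells, falling into 6 groups by construct and doxycycline. In H9 cells, WT, iCas9 and idCas9 lines were each represented by 1 library with and 1 without doxycycline. In H1 cells, iCas9 and WT lines were each represented by 1 library with doxycycline, which made 2 libraries in the groups WT with doxycycline and iCas9 with doxycycline. Reads assigned to genes came to 27.6 M and 23.9 M in H9 iCas9 with and without doxycycline, 26.3 M and 25.4 M in idCas9, 27.0 M and 24.1 M in WT, and 25.1 M and 22.1 M in H1 iCas9 and H1 WT. The H1 libraries stood apart from the H9 libraries in the shape of their values. Their highest RPKM was 103 in both, against 5410 to 9086 in H9, and 18518 and 19623 genes reached 1 RPKM, against 12665 to 13085 in H9. Mitochondrial transcripts took 0.0716% and 0.0872% of the H1 reads and 3.24% to 5.50% of the H9 reads. The H1 iCas9 library was therefore compared with the H1 WT library, both alone and in the fit over both parent lines. The induction fit is an exception. It takes its construct term from H9, so there the H1 difference is set against the H9 difference across these unlike libraries.

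The iCas9 line in H9 expressed antiviral genes, genes of the low-oxygen response and several tissue-restricted genes far above its WT parent, with and without doxycycline. NDUFA4L2, a hypoxia-inducible gene for a mitochondrial protein, rose by 4.18 ± 0.15 (log2, SE; n = 2 libraries per line), from 0.303 and 0.547 RPKM in WT to 25.5 and 24.2 in iCas9 (limma adjusted p = 4.49e-05). The interferon-induced antiviral genes IFIT3, IFIT1 and ISG15 rose by 2.94 ± 0.10, 2.83 ± 0.07 and 2.79 ± 0.07, and ISG15 reached 366 and 394 RPKM against 52.9 and 55.1 in WT. KRT17, a keratin of basal epithelia, NRN1, a promoter of neurite outgrowth, and IGFBP6, which binds insulin-like growth factors, rose by 3.28, 3.16 and 3.02. The other genes that rose most were the cancer-testis genes CSAG3 (2.86) and CSAG1 (2.73), whose near-identical sequences make their separate levels uncertain, and S100A6, a calcium-binding protein (2.83). Among genes that fell, HMX2, a homeobox gene, fell by 1.39, GADD45G, a growth arrest gene, fell by 1.35, and the mitochondrial ATP synthase genes MT-ATP8 and MT-ATP6, which overlap, fell by 1.33 and 1.32. MIR1180 fell by 2.07 and the noncoding RNA D21S2088E fell by 1.47. The small RNAs SNORA28, MIR4482, SNORD73B and MIR186 also passed, at -1.56, -1.48, -1.47 and -1.36. ISG15 (ENSG00000187608) lies on chromosome 1 at 1001138 to 1014540, NDUFA4L2 (ENSG00000185633) on chromosome 12 at 57234903 to 57240715 and IFIT1 (ENSG00000185745) on chromosome 10 at 89392546 to 89406486 (GRCh38). Of 12920 genes tested, limma called 1373 higher and 1087 lower, of which 229 and 43 changed at least 2-fold. The number called fell from 2460 to 650 without the WT library with doxycycline and to 581 without the WT library without it, of which 606 and 550 were among the 2460; with no filter on low genes it was 390.

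By group, the H9 iCas9 line stood above WT in low-oxygen metabolism, sterol synthesis and antiviral genes. Of 31 hypoxia and glycolysis genes, 29 rose and 0 fell, with 30 rising when adjusted over the list alone. NDRG1, a hypoxia marker, rose by 1.90, the glycolytic regulator PFKFB4 by 1.36, the collagen hydroxylase gene P4HA1 by 1.28 and the oxygen sensor EGLN1, in a raised segment of chromosome 1, by 1.15. limma's camera called the list (adjusted p = 5.77e-20), with adjusted p = 0.404 with an estimated correlation. Cholesterol synthesis rose as a group as well, with 18 of 22 genes higher and 19 adjusted over the list alone. Members that rose included the sterol enzyme MSMO1 at 0.81 and INSIG1, a sterol sensor partner, at 0.72 (camera adjusted p = 3.29e-12; adjusted p = 0.404 with an estimated correlation). Interferon-stimulated genes had 13 of 18 members higher, 15 adjusted over the list alone, and a median of 1.51 (camera adjusted p = 3.98e-13; adjusted p = 0.404 with an estimated correlation). In the double-stranded RNA sensing list 5 of 11 members rose and 1 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.0108, and adjusted p = 0.404 with an estimated correlation). The list holds sensors, which trigger interferon, and other genes such as MAVS, TBK1 and IRF3. DDX58 (RIG-I) rose by 1.90, IFIH1 (MDA5) by 1.74 and DHX58 by 1.28. All of these also belong to the interferon-stimulated list, so the lists are not independent.

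**Figure D1:**
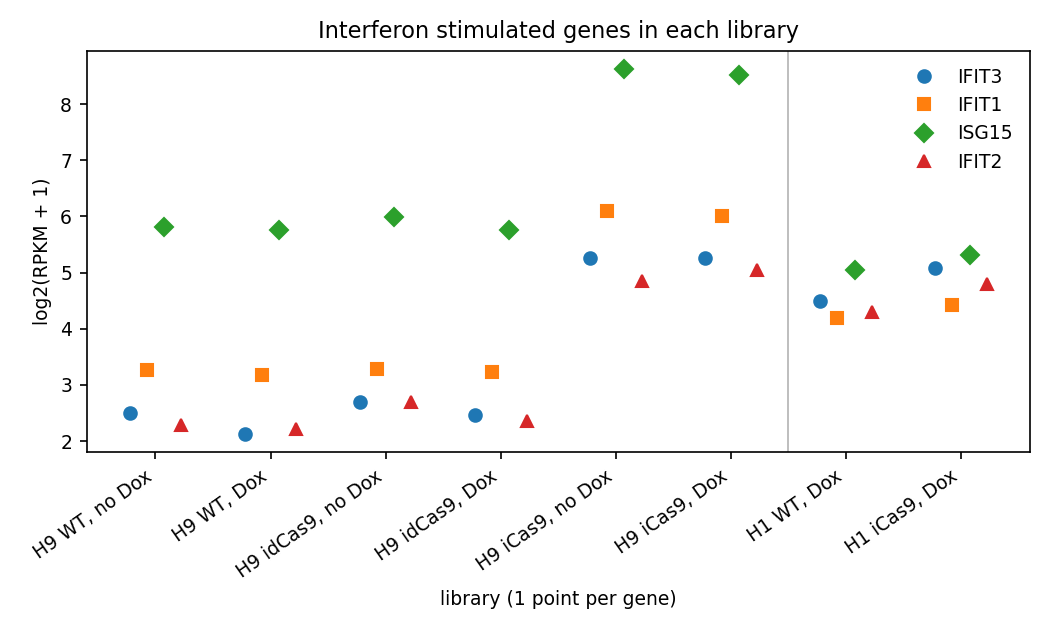
Level of IFIT3, IFIT1, ISG15 and IFIT2 as log2(RPKM + 1) (vertical axis) in each of the 8 libraries (horizontal axis, H9 left and H1 right of the grey line), with 1 point per gene and library. ISG15 (diamonds) stands at 366 and 394 RPKM in the H9 iCas9 libraries and at 52.9 and 55.1 in H9 WT.

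Markers of differentiated tissue moved with these groups. In the mesenchymal and fibroblast list 9 of 14 genes rose, 11 adjusted over the list alone. S100A4, a calcium-binding protein of motile cells, rose by 2.15, vimentin (VIM) by 1.87 and the collagen gene COL6A2 by 1.32 (camera adjusted p = 8.69e-08; adjusted p = 0.404 with an estimated correlation). In the neuronal list 7 of 13 genes rose, 10 adjusted over the list alone, led by the neurofilaments NEFL (1.89) and NEFM (1.69) and by STMN2, a neuronal tubulin regulator (1.56). This list had a camera adjusted p of 1.24e-06, and adjusted p = 0.404 with an estimated correlation. Primed pluripotency genes went both ways, with 10 of 28 higher and 3 lower, and 11 and 3 adjusted over the list alone. LEFTY1, a NODAL antagonist, rose by 1.46 and DPPA2 by 1.13 (camera adjusted p = 0.00272; adjusted p = 0.404 with an estimated correlation). Weaker calls were made for trophectoderm and amnion genes, with 3 of 5 higher, all keratins (KRT8, KRT19 and KRT18), and 3 adjusted over the list alone (camera adjusted p = 0.0354), and for TGF beta and NODAL targets, with 6 of 16 higher and 1 lower, 6 and 1 adjusted over the list alone (camera adjusted p = 0.046). Both had adjusted p = 0.544 with an estimated correlation, and the TGF beta list missed the threshold after median-of-ratios scaling (camera adjusted p = 0.0552).

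Groups that fell in the H9 iCas9 line covered the mitochondrial genome, the entry into DNA replication and stress programmes. Of 13 protein genes of the mitochondrial genome, 10 fell, 12 adjusted over the list alone, with a median of -0.88; MT-CO3 and MT-CO2, subunits of cytochrome c oxidase, fell by 1.05 and 1.03. In the G1/S list, 15 of 26 genes fell, 17 adjusted over the list alone, including the replication licensing gene CDC6 at -0.57 and the replicative helicase gene MCM4 at -0.56, while the cyclin CCND2 rose by 0.99. Both lists had a camera adjusted p of 8.69e-08, and adjusted p = 0.417 with an estimated correlation. Of 29 integrated stress response genes 17 fell, 21 adjusted over the list alone, led by the amino acid transporter SLC7A5 at -1.21 and the serine synthesis enzyme PSAT1 at -1.08. Of 25 p53 targets 11 fell, 16 adjusted over the list alone, among them the growth factor family member GDF15 at -1.06 and the cell cycle inhibitor CDKN1A (p21) at -0.99. Camera adjusted p was 2.98e-07 and 1.86e-06 for these lists, and adjusted p = 0.417 with an estimated correlation for both. Smaller shifts were called for splicing factors, with 10 of 29 lower, and ribosome biogenesis, with 6 of 26 lower, and 10 and 7 adjusted over the list alone. Cytosolic ribosomal proteins were also called, but their single genes do not show a fall, with 2 of 41 higher and 1 adjusted over the list alone. Camera adjusted p for these lists, in this order, was 0.00119, 0.00347 and 0.00597. With an estimated correlation these gave adjusted p = 0.417, adjusted p = 0.404 and adjusted p = 0.665.

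**Figure D2:**
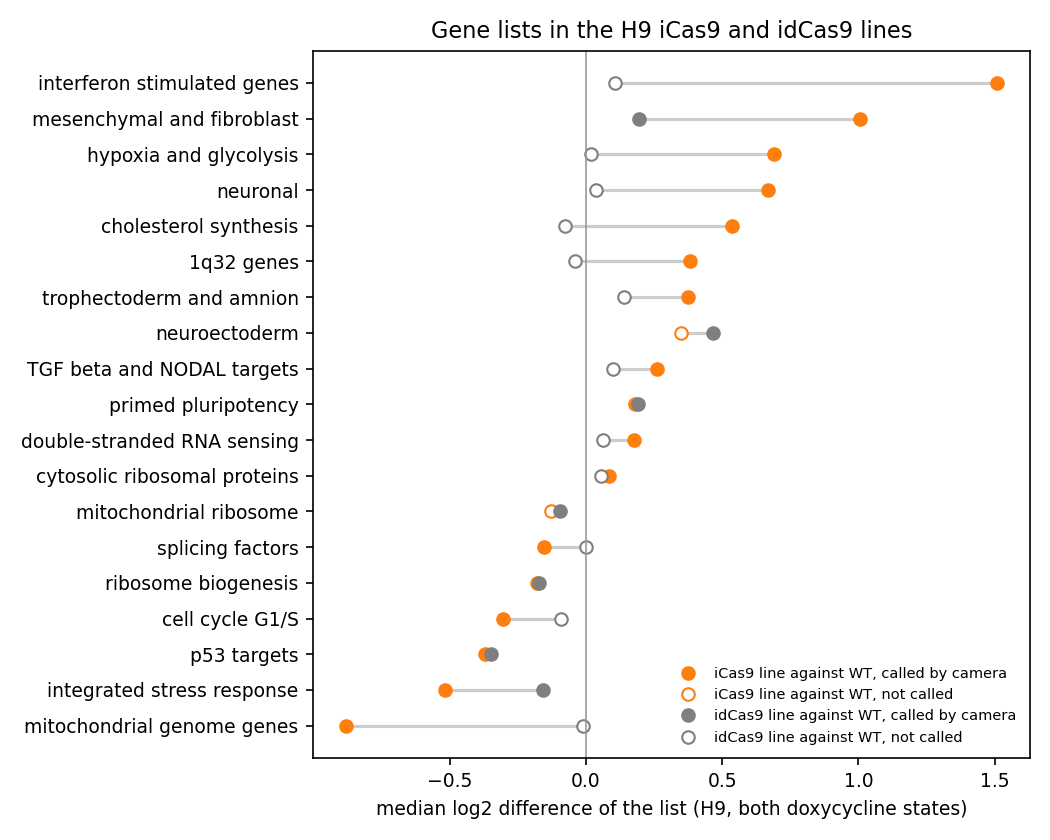
Median log2 difference from H9 WT (horizontal axis) of each gene list that camera called in the H9 iCas9 line (orange) or the H9 idCas9 line (grey), from the fits over the 6 H9 libraries, with filled points where called and open points where not. The interferon list lies at 1.51 in iCas9 and 0.11 in idCas9, and the neuroectoderm list reaches 0.47 in idCas9.

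Several of these genes lie in chromosome regions that shifted as a whole. In the H9 iCas9 line, genes on the long arm of chromosome 1 were higher and genes on distal chromosome 13 were lower than in H9 WT. With doxycycline, 507 protein-coding genes beginning with FAM72C, at 143955364 on chromosome 1, had a median of 0.42, and 93.9% of them lay above 0; genes before 121392822 had a median of -0.03. On chromosome 13, 75 genes beginning with WDFY2, at 51584455, had a median of -0.58, and 2.67% of them lay above 0. Without doxycycline the medians were 0.44 and -0.55. The permutation p was 0.000999 for all 4 breakpoints, the smallest the 1000 permutations can give. Without doxycycline chromosomes 4 and 9 had the same p, with smaller shifts, with medians left and right of the breakpoint of -0.10 and 0.09, and of 0.01 and -0.12, and chromosomes 17 and 8 had a permutation p of 0.002 and 0.003. A small p alone did not mark a segment of a line: H1 iCas9 against WT gave 0.002 on chromosome 8 and 0.003 on chromosome 4, and doxycycline within 1 line gave 0.005 on chromosome 8 in H9 iCas9, and 0.005 on chromosome 6 and 0.00599 on chromosome 8 in H9 WT, with medians on either side between -0.04 and 0.08. In the 6-library fit, 304 of 566 genes tested in the chromosome 1 segment rose and 62 of 96 in the chromosome 13 segment fell. The 1q32 list, 10 of 20 members higher, 11 adjusted over the list alone, with a median of 0.38 (camera adjusted p = 4.04e-07; adjusted p = 0.404 with an estimated correlation), lies inside the chromosome 1 segment. CSRP1, a LIM domain gene of this list, rose by 2.30 and the histone demethylase KDM5B by 1.12. S100A6, S100A4, LEFTY1 and EGLN1, of the hypoxia list, also lie in that segment. In the H9 idCas9 line the same regions had medians of 0.00 and 0.04, and in H1 iCas9 the differences from other genes were -0.01 and 0.00.

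**Figure D3:**
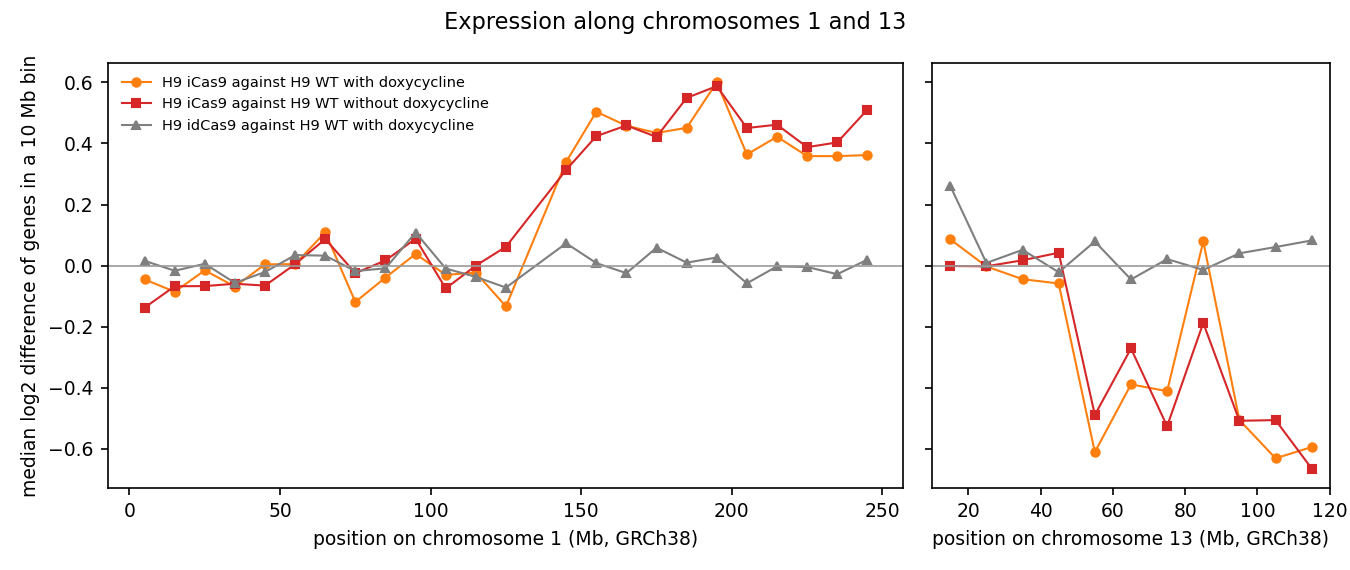
Median log2 difference from WT of protein-coding genes in bins of 10 Mb (vertical axis) by position along chromosomes 1 and 13 (horizontal axes, Mb), for H9 iCas9 with and without doxycycline and H9 idCas9 with doxycycline. With doxycycline H9 iCas9 rises to a median of 0.42 right of the chromosome 1 breakpoint and drops to -0.58 right of the chromosome 13 breakpoint.

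Set against WT library by library, H9 iCas9 had several of the same genes at the top in both doxycycline states. With doxycycline, NDUFA4L2 was higher by 4.35, NRN1 by 3.38, KRT17 by 3.30, S100A6 by 3.15, CSAG3 by 3.13, IFIT3 by 3.12, the urothelial gene UPK1A by 3.02 and IGFBP6 by 2.98. SIX6, an eye-field homeobox gene, was lower by a log2 difference of -1.77; the other 7 lower genes named by the rule were RNAs under 200 nt. Without doxycycline the leading genes were NDUFA4L2 (4.02), KRT17 (3.26), IGFBP6 (3.05) and NRN1 (2.94). At least 2-fold differences numbered 310 higher and 78 lower with doxycycline (protein-coding: 230 and 16) and 248 higher and 108 lower without it (186 and 33), with no replicate check. Among the genes measured in both states, 297 were higher with doxycycline and 240 without it, of which 172 were shared, against 5.55 for independent lists. Of 70 and 108 lower genes 26 were shared, against 0.589. Across 12839 genes, which are not independent replicates, Pearson's r was 0.706 and Spearman's rho was 0.641.

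In H1, interferon-stimulated genes were also higher in iCas9 than in WT. The largest protein-coding differences, chosen after their values were seen, were in GNA14, a G protein subunit, at 1.43 (8.36 against 2.48 RPKM), and the chemokine CCL5 at 1.04. They were followed by the interferon-induced chemokine CXCL10 at 0.97, the interferon IFNL1 at 0.94 and the antiviral enzyme OAS2 at 0.91. All 22 interferon-stimulated genes measured were higher, with a median of 0.42 that lay at percentile 100 of matched random lists. The mesenchymal list was at 0.11 (percentile 99.8). The mitochondrial genome list was at -0.17, but its genes stood at 32 to 84.5 RPKM, near the H1 ceiling. Among genes with at least 1000 nt of exons, reads per base reached at most 1.91 in H1 iCas9 and 1.87 in H1 WT. The larger iCas9 library alone gives genes capped alike a log2 difference of -0.18. The value of the mitochondrial list can therefore not be read as a difference between the lines. Of 1060 other protein-coding genes at a mean of 30 RPKM or more in H1, a limit set after the values were seen, 57 were higher in iCas9. The mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1 were lower by rule, at -2.36 and -2.32. The genes highest by rule were microRNAs and a T cell receptor segment with a median of 9.5 reads in the higher library, such as MIR3139 at 2.76. At least 2-fold differences numbered 215 higher and 66 lower, of which 2 and 0 were protein-coding, and the total of 281 became 113 after median-of-ratios scaling. H9 and H1 differences correlated little across genes, which are not independent replicates (r = 0.0620, rho = 0.0833; protein-coding genes, r = 0.229).

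Taking H9 and H1 as a pair with doxycycline, interferon genes stood higher in iCas9 as a group, although no single gene passed. The H1 libraries, whose values stop near 103 RPKM, make up one side of this pair. Among the 22 interferon-stimulated genes the median was 0.90, with IFIT3 at 1.85, IFIT2 at 1.68 and IFIT1 at 1.53, and limma's camera called the list (adjusted p = 1.82e-13; adjusted p = 0.63 with an estimated correlation). Among the other called lists, hypoxia and glycolysis was at 0.82 in H9 and -0.048 in H1, mesenchymal genes at 0.98 and 0.11, neuronal genes at 0.60 and 0.079, and 1q32 genes at 0.36 and 0.037. Mitochondrial genome genes were at -0.57 in H9, with the H1 value limited by the ceiling. In all, camera called 21 of 40 lists and 0 with an estimated correlation, where the smallest adjusted p was 0.63. limma called 0 of 16248 genes, with 324 higher and 69 lower at an unadjusted p under 0.05. The genes with the smallest p, which did not pass (adjusted p = 0.898), were GNA14 at 1.26 ± 0.16, CXCL10 at 1.25 ± 0.20, TRBJ2-3 at 1.17, MIR1915 at 1.21 and SNORD116-11 at 0.90. The lower ones were MIR3125 at -1.33, MIR3178 at -0.94, SNORD37 at -0.93, MIR6864 at -0.90 and MIR590 at -0.65. Adjusted over the list alone, 2 members of the double-stranded RNA sensing list, 2 definitive endoderm genes and 0 of the interferon-stimulated genes passed. With 1 residual degree of freedom this fit recovered 1% of simulated 2-fold changes.

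In the H9 idCas9 line several transcription factors of early neural development rose above WT. OTX2, a forebrain homeobox gene, rose by 2.31 ± 0.09 (SE; n = 2 libraries per line), from 4.90 and 3.73 RPKM to 26.1 and 24.3 (limma adjusted p = 0.000185). SOX21, a neural progenitor factor, rose by 2.28, the BMP target ID1 by 2.24, the repressor HES3 by 1.92 and the forebrain gene FEZF1 by 1.92. CYP26A1, which degrades retinoic acid, rose by 1.93, COL1A1 by 1.88, the neuronal pentraxin NPTX1 by 1.86, and the microRNAs MIR302C and MIR548AR by 2.39 and 1.89. Genes that fell included INPP5F, a phosphoinositide phosphatase, at -1.47, MAGEE1 at -1.44, the peptide hormone APLN at -1.25 and CDKN1A at -1.14. The GABA receptor subunit GABRA3 fell by 1.12, GDF15 by 1.11, the growth factor PDGFB by 1.08 and the cancer-testis gene MAGEA4 by 1.03. MIR1180 fell by 1.74, and SNORD53B also passed. OTX2 (ENSG00000165588) lies on chromosome 14 at 56799905 to 56810479. limma called 235 genes higher and 61 lower of 12920, of which 78 and 14 changed at least 2-fold. The total of 296 fell to 51 and 62 without the WT library lacking and having doxycycline, to 94 and 150 without the respective idCas9 library, and to 7 with no filter, and rose to 1099 and 1130 without either iCas9 library and to 546 among protein-coding genes.

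In groups, 6 of 13 neuroectoderm genes rose in idCas9, 10 adjusted over the list alone, with IRX2, a patterning factor, at 1.59 (camera adjusted p = 7.84e-09; adjusted p = 0.53 with an estimated correlation). Primed pluripotency genes rose in 6 of 28 cases, 14 adjusted over the list alone, including PRDM14 at 0.91 and SOX2 at 0.60, while the surface marker THY1 fell by 0.62 (camera adjusted p = 0.000283; adjusted p = 0.536 with an estimated correlation). OTX2 belongs to both lists. Of 25 p53 targets 4 fell, 16 adjusted over the list alone, with BTG2, an antiproliferative gene, at -0.82 (camera adjusted p = 2.57e-12; adjusted p = 0.737 with an estimated correlation). The fall of this list in both constructs was measured against the same WT libraries. In the mesenchymal list 4 of 14 rose and 1 fell, 6 and 2 adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.737 with an estimated correlation). Ribosome biogenesis had a median of -0.17 with 0 of 26 members past the threshold, 6 lower adjusted over the list alone (camera adjusted p = 2.01e-06; adjusted p = 0.53 with an estimated correlation). The integrated stress response list, with 1 of 29 lower, and the mitochondrial ribosome list, with 0 of 24, had the same counts adjusted over the list alone, with camera adjusted p of 0.00094 and 0.00953, and adjusted p = 0.737 with an estimated correlation for both. Interferon-stimulated genes had a median of 0.11 and 1 of 18 members higher, BST2, an antiviral membrane protein, at 0.93; camera did not call the list (adjusted p = 0.0807). Library against library, 127 genes were at least 2-fold higher and 46 lower with doxycycline (protein-coding: 50 and 8), led by MIR367 at 2.51 and SOX21 at 2.44. Without doxycycline there were 121 and 54 (70 and 5), led by MIR302C at 2.84 and MIR302A at 2.71. Across genes the states correlated at r = 0.490 and rho = 0.414, with 66 higher genes in common against 1.13 for independent lists.

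Tested directly against each other in H9, iCas9 exceeded idCas9 in antiviral, hypoxia and neuronal genes at the preset correlation of the list test, while single regulators of neural development such as SOX21, HES3 and OTX2 were higher in idCas9. NDUFA4L2 was higher in iCas9 by 3.54 ± 0.15, NRN1 by 3.19, KRT17 by 3.09, BEX5, a brain-expressed X-linked gene, by 3.04, and IFIT1 by 2.80 ± 0.07 (limma adjusted p = 1.88e-05 for IFIT1). CH25H, an interferon-induced cholesterol hydroxylase, was higher by 2.74, as 11.4 and 11.5 RPKM against 0.969 and 0.748. GADD45G was lower in iCas9 by log2 differences of -2.36, SOX21 by -2.28, ID1 by -2.24, IRX2 by -2.06, HES3 by -2.02, FEZF1 by -1.99 and OTX2 by -1.72. SOX21 lies in the chromosome 13 segment that was lower in iCas9. It was hardly expressed in iCas9 (0.156 and 0.0904 RPKM with and without doxycycline) and in WT (0.0533 and 0.194). In idCas9 it stood at 4.7 and 4.2 RPKM, so its difference lies in the rise in idCas9. Of 12920 genes, limma called 1079 higher and 871 lower, of which 188 and 70 differed at least 2-fold; the total of 1950 became 919 and 873 without either idCas9 library and 250 with no filter. Hypoxia and glycolysis (26 of 31 higher, 28 adjusted over the list alone) and cholesterol synthesis (20 of 22 higher, 20 adjusted over the list alone) had camera adjusted p of 1.84e-19 and 1.8e-15, with adjusted p = 0.477 and adjusted p = 0.454 with an estimated correlation. Interferon-stimulated genes, 13 of 18 higher and 1 lower, 14 and 1 adjusted over the list alone, had a camera adjusted p of 2.9e-12, and adjusted p = 0.454 with an estimated correlation. Neuronal genes, 9 of 13 higher, 11 adjusted over the list alone, had a median of 0.82 (camera adjusted p = 2.92e-08; adjusted p = 0.454 with an estimated correlation). Neuroectoderm genes went both ways, with 6 of 13 lower and 2 higher, 7 and 3 adjusted over the list alone (camera adjusted p = 0.0259; adjusted p = 0.477 with an estimated correlation). Of the 38 lists tested, 0 were called with an estimated correlation. With doxycycline, 111 genes were at least 2-fold higher in the idCas9 library than in the iCas9 library and 258 lower (protein-coding: 44 and 199).

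With doxycycline, glycolysis genes stood lower and amino acid stress genes higher as groups, while no single gene passed the test. Of 31 hypoxia and glycolysis genes 9 were lower adjusted over the list alone, with a median of -0.15 (limma's camera adjusted p = 2.71e-15), and of 29 integrated stress response genes 8 were higher, with a median of 0.19 (camera adjusted p = 3.59e-08). Both had adjusted p = 0.699 with an estimated correlation. Over the 3 H9 lines PGK1, a glycolytic enzyme, had a log2 change of -0.48 ± 0.06 (limma adjusted p = 0.216, lower in 3 of 3 lines) and PSAT1 one of 0.41 ± 0.07 (adjusted p = 0.459, higher in 3 of 3 lines). limma called 0 of 12920 genes, with 569 higher and 406 lower at an unadjusted p under 0.05. The genes with the smallest p, none of which passed (limma adjusted p = 0.107 to 0.46), also included LRAT, a retinol-esterifying enzyme (0.47), MIR3124 (adjusted p = 0.107), SNORD73B (1.17) and SNORD93 (1.52), and APLN (-0.53), GRPR, a bombesin-family receptor (-0.74), PDGFB (-0.39) and MIR7856 (-1.02). TRIB3, a stress kinase homologue, was at 0.40 and the cystine transporter SLC7A11 at 0.38. In all, camera called 8 of 38 lists and 0 with an estimated correlation. Without the iCas9 library with or without doxycycline, limma called 94 and 91 genes. With line as a block, both runs compare the drug in idCas9 and WT, since the remaining iCas9 library has no partner, so they do not check each other. Without either idCas9 library it called 1, the small nucleolar RNA RF00569 at -1.22, and at a filter of 5 RPKM 1, the pseudogene SLC7A5P1 at 0.75, both chosen after their values were seen.

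Within single lines, few protein-coding genes differed at least 2-fold with the drug. In H9 iCas9, where doxycycline induces Cas9, the glycosyltransferase GALNT16 (1.39), the kinase DYRK3 (1.15), the DNA methylation factor UHRF1 (1.12) and the NODAL targets LEFTY1 (1.07), CER1 (1.06) and LEFTY2 (1.01) were higher, and GRPR was lower (-1.04). TGF beta and NODAL targets had a median of 0.34 and mitochondrial genome genes 0.36 (both percentile 100), while p53 targets were at -0.23 (percentile 0). In H9 idCas9, the hormone gene SCT (-1.11), the ephrin EFNA1 (-1.01) and VPREB3 (0.402 against 1.81 RPKM) were lower. In H9 WT the lipase inhibitor G0S2 was higher (1.57). These protein-coding names were chosen after their values were seen; the rule named 8 genes per line and direction, of which 7 or 8 were RNAs under 200 nt, with 5.5 to 13.5 reads at the median in the higher library, such as SNORD12C (2.34) and SNORD117 (-2.69) in iCas9, MIR590 (2.08) and MIR320C2 (-2.52) in idCas9, and MIR106B (2.21) and SNORD6 (-1.93) in WT. Integrated stress response genes were at 0.089 in iCas9 (percentile 88.8), 0.20 in idCas9 and 0.24 in WT, and hypoxia and glycolysis at -0.055 in iCas9 and -0.20 in the other two. Mitochondrial genome genes were at 0.16 in idCas9 and -0.23 in WT. At least 2-fold differences numbered 54 higher and 38 lower in iCas9, 48 and 24 in idCas9, and 35 and 41 in WT, of which 7 and 1, 0 and 3, and 1 and 0 were protein-coding. Higher genes shared between lines numbered 7 for iCas9 and idCas9, 1 for iCas9 and WT and 5 for idCas9 and WT, against 0.166, 0.0897 and 0.102 for independent lists. Lower ones numbered 2, 6 and 0, against 0.0469, 0.0741 and 0.0591. These expected numbers take every gene as equally likely to reach 2-fold. RNAs under 200 nt, which rest on few reads, made up 56 of 92 such genes in iCas9, 53 of 72 in idCas9 and 58 of 76 in WT. Among protein-coding genes, few of which reached 2-fold, 0 were shared in any pair. The excess can therefore not be read as a shared drug response. Across genes the drug responses correlated at r = 0.0804 between iCas9 and idCas9, 0.0732 between iCas9 and WT and 0.0482 between idCas9 and WT, with rho of 0.0722, 0.105 and 0.0818.

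Induction of Cas9 or dCas9 beyond the effects of the drug and the line went with higher mitochondrial transcripts and lower ribosomal protein transcripts as groups, and with no single gene past the threshold. Mitochondrial genome genes had a median of 0.65 and cytosolic ribosomal proteins one of -0.14 (RPLP0 -0.28), with camera adjusted p of 6.1e-10 and 5.32e-09, adjusted p = 0.771 with an estimated correlation for both, and 0 members past the threshold, as adjusted over the list alone. The 0.65 includes H1 mitochondrial values near the H1 ceiling. Without the H1 libraries, which have no drug-free partner, the mitochondrial median was 0.40 and the ribosomal median -0.10. With the drug, mitochondrial reads rose from 3.24% to 3.69% in H9 iCas9 and from 4.95% to 5.15% in idCas9. They fell from 5.50% to 4.91% in the only H9 WT pair, so the H9 estimate rests in part on that pair, which has no replicate. Interferon-stimulated genes had a median of -0.37 (ISG15 -1.10, IFIT1 -1.02; camera adjusted p = 0.0056; adjusted p = 0.771 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. Without the H1 libraries this median was -0.02, and IFIT1 turned to 0.03. Primed pluripotency genes were at -0.14 with the H1 libraries (camera adjusted p = 0.00047; adjusted p = 0.771 with an estimated correlation; 0 members passed adjusted over the list alone), and at -0.040 without them, where camera no longer called the list (adjusted p = 0.19). camera called 10 of 39 lists with the H1 libraries and 6 without them, the latter including p53 targets at -0.15 (camera adjusted p = 0.000343) and integrated stress response genes at -0.14 (camera adjusted p = 0.000309). Without the H1 libraries 0 lists were called with an estimated correlation, where both of these had adjusted p = 0.97 with an estimated correlation. limma called 0 of 14573 genes, with 347 higher and 131 lower at an unadjusted p under 0.05. The smallest p belonged to TRBJ2-3 (1.32), MIR25 (1.11), SNORD17 (1.35), MIR647 (2.22) and RNVU1-7 (1.65), and on the lower side to MIR1244-4 (-1.48), MIR302A (-1.99), MIR3682 (-2.01), the tendon factor SCX (-0.77) and the pluripotency regulator PRDM14 (-0.62), none of which passed (limma adjusted p = 0.935 to 0.998).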

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

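All tests of explanations in this part were chosen after the result was seen, except those of expression level and gene length, of chromosome 1 gene dosage and of removal of reads at equal positions.

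The iCas9 and idCas9 lines in H9 differed from WT in different ways, by the direct test of iCas9 against idCas9. This comparison called 1079 genes higher and 871 lower in iCas9. Genes higher in iCas9 were NDUFA4L2 (3.54), NRN1 (3.19), KRT17 (3.09), BEX5 (3.04), IFIT1 (2.80), CSAG3 (2.74), CH25H (2.74), CSAG1 (2.72), ISG15 (2.69) and IFIT3 (2.68). Lower ones were GADD45G (-2.36), SOX21 (-2.28), ID1 (-2.24), IRX2 (-2.06), HES3 (-2.02), FEZF1 (-1.99), MIR647 (-1.92), the phospholipase-like PLCL2 (-1.92), C5orf38 (-1.88) and OTX2 (-1.72). SOX21 lies in the chromosome 13 segment that was lower in iCas9, but it was hardly expressed in WT too, so its difference lies in the rise in idCas9. The totals became 919 and 873 without the idCas9 library with and without doxycycline.

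Gene lists differed between the lines as well. Median log2 differences were 1.41 for interferon-stimulated genes, 0.82 for neuronal, 0.64 for hypoxia and glycolysis, 0.62 for cholesterol synthesis, 0.54 for mesenchymal, 0.45 for 1q32, 0.24 for immediate early, 0.10 for G2/M and 0.093 for double-stranded RNA sensing genes. They were -0.83 for mitochondrial genome genes, -0.44 for neuroectoderm, -0.34 for the integrated stress response, -0.32 for G1/S and -0.15 for splicing factors. Among immediate early genes EGR1, a growth-induced transcription factor, was lower (-1.53) and DUSP5 and JUN were higher (1.19 and 1.05). The call for double-stranded RNA sensing was lost after median-of-ratios scaling (limma's camera adjusted p = 0.0741). With an estimated correlation 0 of these lists were called.

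For induction, which asks whether Cas9 or dCas9 lines respond to doxycycline differently from WT, limma's camera called 10 lists, and 0 with an estimated correlation. Their medians were 0.65 for mitochondrial genome genes, 0.14 for splicing factors, -0.37 for interferon-stimulated genes, -0.22 for hypoxia and glycolysis, -0.20 for neuronal, -0.17 for G2/M, -0.15 for cholesterol synthesis, -0.14 for both primed pluripotency and cytosolic ribosomal proteins, and -0.12 for 1q32 genes. The H1 mitochondrial values lie near the H1 ceiling. Without the H1 libraries camera no longer called interferon-stimulated (-0.02), hypoxia and glycolysis (0.04), neuronal (0.03), cholesterol synthesis (0.04), primed pluripotency (-0.040) and 1q32 genes (0.01). It still called mitochondrial genome genes (0.40), splicing factors (0.10), G2/M (-0.14) and cytosolic ribosomal protein genes (-0.10).

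Some lists went opposite ways in H9 and H1 for iCas9 against WT with doxycycline, a difference that was not tested. Cholesterol synthesis was at -0.070 in H1 and 0.54 in H9, hypoxia and glycolysis at -0.048 and 0.82, the integrated stress response at 0.020 and -0.60, p53 targets at 0.041 and -0.49, and replication-dependent histones at -0.13 and 0.05. The H1 histone value is limited by the H1 ceiling, since the list's genes reached 89.6 RPKM there and the larger H1 iCas9 library alone gives capped genes a log2 difference of -0.18. Of 1060 other protein-coding genes at a mean of 30 RPKM or more in H1, 57 were higher in iCas9, with a median of -0.073. PGK1 stood at 26.6 and 28.3 RPKM in H1 iCas9 and WT, against 429 and 197 in H9. The H1 values of cholesterol synthesis and of hypoxia and glycolysis can therefore not be told apart from the ceiling.

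In the H9 iCas9 line, genes of the long arm of chromosome 1 were higher and genes of distal chromosome 13 lower. A few strongly changed genes cannot account for this, since at least 92.49% of the genes of either segment lay on the side of its shift. Expression level and gene length are argued against too: among 1000 matched sets the highest median was 0.0243 for chromosome 1, against 0.42 in the segment, and the lowest was -0.10 for chromosome 13, against -0.58. A changed copy number in the H9 iCas9 line, which may have been gained in culture or during line making, stays open, because the breakpoints with and without doxycycline lay within 2 genes of each other on chromosome 1 and 0 on chromosome 13. DNA was not analysed here.

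Interferon-stimulated genes were higher in the iCas9 lines. Doxycycline moved the list in H9 iCas9 by a median of 0.04753, 1 library against 1, while the difference from WT was 1.48. In H9 the difference was thus present without the drug. This cannot decide whether Cas9 is the cause, since its level, with or without the drug, was not analysed. H1 iCas9 has no library without doxycycline, so the drug's effect there is unknown. Of the 13 called members 0 lie in the chromosome 1 segment, so its gene dosage did not raise them directly. Where the list's genes lie fixed this outcome. Whether other genes of the segment raised the list indirectly was not tested. Presence of the iCas9 construct may contribute, as the list was also higher in H1 iCas9, at a median of 0.4235. The H9 idCas9 line carries a construct brought in the same way, but its list median was far smaller and camera did not call it. Parts shared by both constructs thus did not raise the list to the same extent there. Differences between cultures or clones of each line stay open, with 1 iCas9 line per parent.

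H1 values ended near a ceiling and held many histone transcripts. Lower depth is argued against, because the smaller H1 library held 0.9253 times the reads of the smallest H9 library. Removal of reads at equal positions may have set the ceiling, as the slope of H1 on H9 log2 values was 0.115 over the most highly expressed protein-coding genes and 0.646 over the middle. RNA without a poly(A) tail is a candidate source of the histone transcripts, whose median log2 ratio of H1 to H9 was 3.40, at percentile 100 of matched lists. No biological explanation was tested for this pattern.

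The 6 H9 libraries can be split in 10 ways for doxycycline, too few for a share under 0.05; the real split called 0 genes and the highest other split 0. At an unadjusted p under 0.05 they called 975 and 1555. The splits with 1555 part only the iCas9 pair, so with line as a block they are the drug contrast within iCas9. They are therefore no neutral regrouping. The other splits that part all pairs, as the real one does, called 459, 500 and 457. Splits that part the same single pair gave the same fit, so the 10 are not all distinct. For induction, 52 of 52 splits called as many genes as the real one, which had to be so because the real split called 0, and the count says nothing about chance. The highest other split called 0 too. The real and the highest other split called 478 and 2062 at an unadjusted p under 0.05. Given the terms of the fit, the split with 2062 sets the iCas9 difference from WT in H1 against that in H9, so it is no neutral regrouping. Some other splits are the same fit as the real one and also called 478. The cause of these counts was not tested.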

How the results depend on the processing

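The comparisons between H9 lines, the settings for protein-coding genes and exon length, and the list tests of induction without H1 were chosen after seeing the data. Of the leading results, 82 values stayed within 1.5 times or within their interval and 84 moved. Values for single genes and for the chromosome segments in H9 iCas9 against WT were counted too. Of these, 4194 kept direction and side of the threshold, 217 lost and 50 gained significance, 47 moved and 19 reversed. All of the reversed values were those of single genes. List medians are not in this count: for induction, those of hypoxia and glycolysis (0.04), neuronal (0.03), cholesterol synthesis (0.04) and 1q32 genes (0.01) turned from negative without the H1 libraries. Leaving out the replicate block changed no other call than the unadjusted counts given with the pairing check. The lone library left in an arm was assumed to vary like the other groups. For iCas9 against WT over H9 and H1, leaving out a library left no residual degrees of freedom, so each line alone is a value with no test, and induction could not be fitted without the WT library lacking doxycycline. Depth limits the RNAs under 200 nt, which rest on few reads.

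With each library left out in turn, the number of genes called ranged from 0 to 94 for doxycycline (94 and 91 without the iCas9 library with and without doxycycline, 1 without either idCas9 library; the library left in a line then has no partner and adds nothing to the drug effect), from 581 to 2886 for the iCas9 line (650 and 581 without the WT library with and without doxycycline), from 51 to 1130 for the idCas9 line (1130 and 1099 without the iCas9, 150 and 94 without the idCas9, and 62 and 51 without the WT library with and without doxycycline), and from 873 to 2640 for iCas9 against idCas9 (919 and 873 without the idCas9 library with and without doxycycline). At a mean RPKM of at least 5 limma called 1 gene for doxycycline. With no filter it called 390 for the iCas9 line, 7 for the idCas9 line and 250 between them; more genes were tested there, but the cause was not tested. Among protein-coding genes the idCas9 line had 546. With an estimated correlation 0 lists were called in any of the 6 fits, and without the H1 libraries 6 lists were called for induction, 0 with an estimated correlation. With so few residual degrees of freedom that setting could hardly call any list, so its lack of calls does not decide whether the lists shifted.

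The number of genes differing at least 2-fold in the pairs of libraries depended on the setting. With a pseudocount of 0.1 it was 259 for doxycycline in iCas9, 201 in idCas9 and 207 in WT. For iCas9 against WT it was 755 and 726 in H9 with and without doxycycline and 738 in H1, for idCas9 against WT 389 and 373, and for idCas9 against iCas9 698. In the same order a mean RPKM of at least 5 gave 11, 7, 8, 156, 154, 12, 51, 52 and 165. A limit of 1.5-fold gave 416, 286, 273, 1339, 1368, 989, 627, 598 and 1250, and protein-coding genes gave 8, 3, 1, 246, 219, 2, 58, 75 and 243. Exons of at least 200 nt gave 36, 19 and 18 for doxycycline, 61 for H1 iCas9, and 103 and 115 for idCas9 against WT with and without doxycycline. Median-of-ratios scaling gave 113 for H1 iCas9. Fewer genes enter under the filters; for the pseudocount and scaling the cause was not tested. Of the named genes in these pairs, 45 moved with the pseudocount and 2 with the scaling.

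Correlations across genes changed as well, given for a pseudocount of 0.1, a mean RPKM of at least 5 and protein-coding genes. For doxycycline they were 0.0486, 0.168 and 0.0973 between iCas9 and WT, and 0.0201, 0.0725 and 0.133 between idCas9 and WT. For iCas9 against WT they were 0.0359, 0.167 and 0.229 between H9 and H1, and 0.632, 0.822 and 0.797 between doxycycline states. For idCas9 against WT they were 0.415, 0.642 and 0.635 between doxycycline states. The cause was not tested.

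The reversed values themselves were at most 0.21. For induction without the H1 libraries, or without either of them, CSRP1 was at 0.15, KDM5B at 0.088, IFIT1 at 0.032, IFIT2 at 0.0098 and NEFM at 0.031, the highest values with any library left out. The lowest, without the H9 WT library with doxycycline, were -2.24, -1.08, -2.59, -2.19 and -1.60. In this fit the H1 libraries carry construct and induction together. GDF3 was at 0.043 for idCas9 alone and without the H9 iCas9 library lacking doxycycline, and at -1.22 without the H9 WT library with doxycycline. GABRP in the iCas9 line was at 0.21 without the iCas9 library and 0.066 without the WT library lacking doxycycline, and at -0.24 without the iCas9 library with doxycycline; it passed in none of these, and the cause was not tested.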

Other observations

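The genes in this part were chosen after their values were seen, and no explanation was tested.

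In the H9 libraries POU5F1, a core pluripotency factor, stood at 740 and 782 RPKM in iCas9 with and without doxycycline, 673 and 700 in idCas9 and 781 and 738 in WT. SOX2, which also marks neural progenitors, stood at 153 and 134 in iCas9, 153 and 153 in idCas9 and 101 and 99.3 in WT. Genes that repress transposable elements and KRAB zinc finger genes had medians of -0.01 and 0.01 in the H9 iCas9 line, and limma's camera called neither list.

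The double-stranded RNA sensors IFIH1 and DDX58 were higher in iCas9 in both parent lines. IFIH1 stood at 5.43 and 5.66 RPKM in H9 iCas9 against 0.930 and 0.994 in H9 WT, and at 9.44 in H1 iCas9 against 5.24 in H1 WT. DDX58 stood at 9.91 and 10.2 against 2.15 and 1.77 in H9, and at 16.2 against 11.4 in H1. COL1A1, type I collagen, was higher in both H9 constructs, at 14.5 and 18.4 RPKM in iCas9 and 13.7 and 17.6 in idCas9 against 2.83 and 4.24 in WT, which both share as control.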
